A study of Mus musculus with 6 samples.

How the data were processed

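Gene expression was measured in tibialis anterior muscle of 16-week-old ICR mice, an outbred strain. Per the labels' protocols, sections were stained for acetylcholinesterase activity on ice for 10 min, 9973 neuromuscular junctions (NMJs) were cut out by laser capture, and an equal area away from the junctions was taken from the same fibres. RNA was amplified from 10 ng per sample and hybridised, labelled with biotin, to Affymetrix mouse exon arrays, 1 array per sample. Region labels in the sample descriptions gave 3 NMJ arrays and 3 non-NMJ arrays. The labels used here do not give the number of animals or say whether a replicate number marks an animal. The p-values therefore measure the spread between these samples, and are too small if arrays of the same region share animals. Per the protocols, both regions came from the same fibres, and so from the same animals. Which NMJ array matches which non-NMJ array is not given. The fit ignores this sharing of animals between the regions, so the p-values may also be too large.

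The deposited values are gene-level expression values on a log2 scale, which the authors made with RMA (background correction, normalization and summary of probes into 1 value per gene-level row). Per the submitters' processing notes, the programs were Affymetrix Expression Console and Transcriptome Analysis Console. Their versions, their settings and the genome build are not given in the sources used here. The log2 scale was read from the values, which ran from 0.87 to 13.971. Exon-level values were not analysed here, so splice differences were outside the analysis. No detection calls were used, so the level at which a row stood above background is unknown. RMA compresses differences in very dim and very bright rows, and the number of arrays limits the precision.

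The table held 23332 rows, all of which were tested. The platform's gene table listed 16015 of them: 14996 carried 1 gene symbol (14860 distinct symbols) and 1019 carried several. The remaining 7317 were unnamed here. Of the rows with 1 symbol, 14941 matched the RefSeq gene table of GRCm38.p6 by gene identifier, and 0 symbols changed. That table was used only for names and for the order of genes along chromosomes, since no build was named for the array values; no coordinates are given. Genes were named only from rows with 1 symbol. Colq had no such row and was not analysed here.

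Differences are NMJ minus non-NMJ. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, both directions tested), with no term for the replicate number. P-values were adjusted by the Benjamini-Hochberg method over all rows, and a row was called at an adjusted p under 0.05. A fold is 2 raised to the log2 difference. Errors of differences are standard errors (SE) of the fit. The arrays were also compared by Pearson correlation and principal components over all rows.

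Gene lists for synaptic proteins, fibre metabolism, signalling and the cell types of muscle were fixed before the data were examined: 23 were written and 22 tested. The red blood cell list had fewer than 3 measured members. A gene with several rows took the row with the highest mean. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move on balance in 1 direction, not whether they differ from other genes.

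Genes were named by a rule fixed at the same time. It took the 10 largest differences each way among called rows whose groups did not overlap, leaving out placeholder names. Called rows with such names numbered 36 higher and 40 lower, whatever the size of their difference. It added Chrna1, Chrne, Musk, Lrp4, Rapsn, Dok7, Ache, Utrn, Etv5, Rspo2, Lgr5, Ccn2 and Prkar1a whatever their values. From each list it took up to 4 members with the smallest unadjusted p. Further members, named as the few exceptions to a count, were picked after their values were seen.

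On simulated data of 23332 rows with the spread of these arrays, the limma step recovered 7.6% of 66 rows changed by 0.5 on the log2 scale, 53.7% of 67 changed by 1 and 88.1% of 67 changed by 2. It made 2 false calls, and 0 calls when nothing was changed. When 5364 rows were changed by 1, it recovered 85.1%, with 4.1% of calls false. A simulated list shifted by 0.5 had a camera adjusted p of 5.57e-18, and 0.0193 with an estimated correlation. The alternatives were the replicate number as a block, quantile normalization, median centring, filters on dim or unnamed rows, other variance models, array weights, other thresholds, other list tests and the omission of each array in turn.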

Results

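The series compared muscle tissue captured at neuromuscular junctions with tissue captured elsewhere along the same fibres of the mouse tibialis anterior, a fast leg muscle. The question was which transcripts differ between the synaptic and extrasynaptic regions. There were 3 arrays of each region. Median log2 values were 4.516, 4.53 and 4.491 on the NMJ arrays and 4.372, 4.38 and 4.366 on the non-NMJ arrays. Pearson correlations over all rows ranged from 0.988 to 0.990 among NMJ arrays, from 0.980 to 0.983 among non-NMJ arrays and from 0.953 to 0.961 between the regions. The first principal component held 63.5% of the variance and separated the regions.

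The genes of the acetylcholine receptor were among those with the largest differences. Chrna1, which encodes the alpha subunit of the muscle receptor, was 59.5-fold higher in NMJ regions (log2 difference 5.89 ± 0.17, SE, n = 3 per region). Chrne, the subunit of the adult receptor, was 56.9-fold higher, and Etv5, an ETS transcription factor active in synaptic nuclei, was 52.7-fold higher. In the other direction, Amy1, an amylase gene, had the largest decrease among the genes that the naming rule allowed. It fell by 3.46 ± 0.19 (SE) on the log2 scale in NMJ regions. Car3, a cytosolic carbonic anhydrase abundant in muscle, was 8.28-fold lower, and Mstn, the secreted inhibitor of muscle growth, was 7.58-fold lower.

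In total 5364 of 23332 rows (23%) were called by limma at an adjusted p under 0.05, 3351 higher and 2013 lower in NMJ regions. Of these, 1285 were at least 2-fold higher and 356 at least 2-fold lower, and 112 and 9 were at least 8-fold higher and lower. The groups did not overlap in 41% of all rows, where chance gives 10%. The share of calls that were higher was 62.5%, against 46.6% after quantile normalization and 41.7% after median centring, which moved the median difference of all rows from -0.01 to -0.15. Omission of NMJ replicate 1 or 2 left 3373 or 3535 calls.

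**Figure D1:**
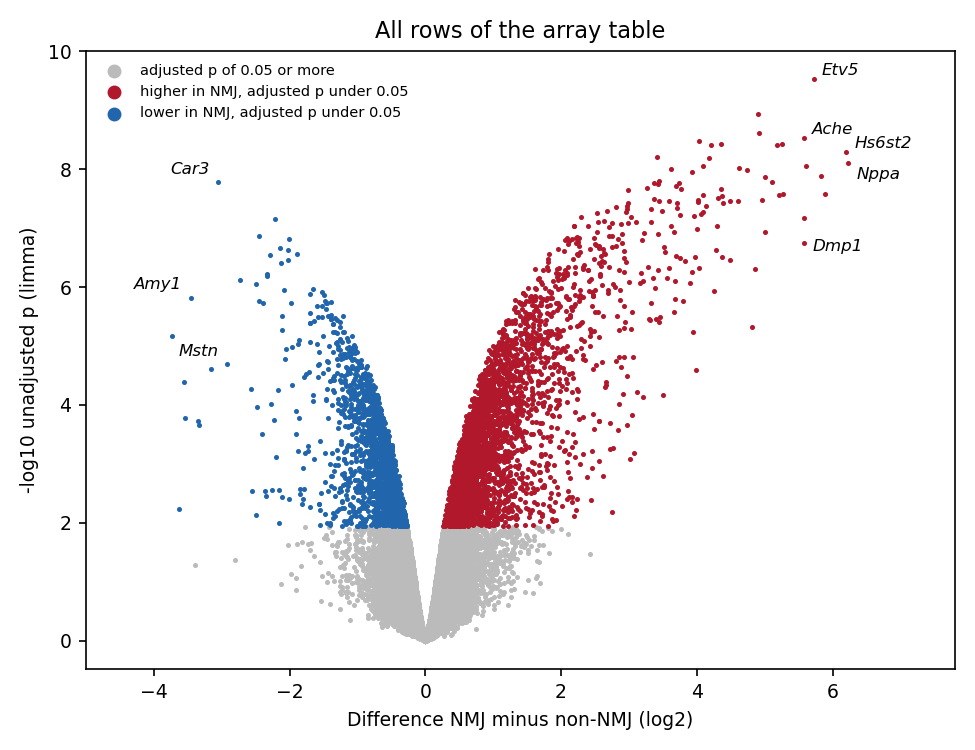
Each point is 1 of the 23332 rows, with the log2 difference (NMJ minus non-NMJ) on the x axis and the -log10 unadjusted p from limma on the y axis. Red and blue mark the 3351 higher and 2013 lower rows with an adjusted p under 0.05; Nppa, Hs6st2, Etv5, Ache and Dmp1 lie far right, and Amy1, Car3 and Mstn lie left.

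Among the genes that the naming rule allowed, the largest increase was in Nppa (row 6918692), which encodes the atrial natriuretic peptide precursor. Its mean log2 value was 11.18 ± 0.10 (SD, n = 3) in NMJ regions and 4.95 ± 0.25 (SD, n = 3) in non-NMJ regions, a 75.1-fold difference (limma adjusted p = 1.36e-05). Hs6st2 (row 7016808), a heparan sulfate 6-O-sulfotransferase, was 73.6-fold higher, with a log2 difference of 6.20 ± 0.13 (SE). Ncam1, the neural cell adhesion molecule, was 48.7-fold higher, and Chrnd, the delta subunit of the receptor, was 48.0-fold higher. Dmp1, a secreted acidic phosphoprotein best known from bone and dentin, was 47.9-fold higher. Ache, the acetylcholinesterase gene, was 47.6-fold higher; staining for this enzyme guided the capture, so its difference is no separate finding. Ufsp1, a cysteine peptidase gene, was 38.5-fold higher. The non-NMJ means of Hs6st2 (3.52), Dmp1 (3.81) and Chrnd (4.27) lay below the medians of those arrays, where the level over background is unknown, so their folds and ranks are only those of the RMA values. Chrna1 (row 6887853), Chrne (row 6789441) and Etv5 (row 6844558) complete these 10 genes, and their adjusted p-values in limma lay between 6.83e-06 and 1.77e-05.

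Among the 10 genes that the rule took for their decreases, Amy1 (row 6908350) fell from a mean log2 value of 7.37 ± 0.25 to 3.91 ± 0.28 (SD, n = 3). Car3 (row 6895855) fell by 3.05 ± 0.08 (SE) on the log2 scale, from 12.40 to 9.35. Mstn (row 6749461) fell by 2.92 ± 0.25 (SE), with a limma adjusted p of 6.94e-04. Mettl21e, a methyltransferase gene of muscle, was 6.61-fold lower, and Sprr1a, a small proline-rich protein gene, was 5.96-fold lower. Npr3, the natriuretic peptide clearance receptor, was 5.49-fold lower, and the kinase gene Map2k6 was 5.23-fold lower. Slc38a3, an amino acid transporter that carries glutamine, was 5.06-fold lower. Tspan8, a tetraspanin, was 5.04-fold lower, and Sgk1, a kinase induced by glucocorticoids, was 4.90-fold lower. The NMJ means of Amy1 (3.91) and Sprr1a (3.22) lay below the medians of those arrays, so the same limit holds for their folds.

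Genes of the receptor and its clustering rose as a group. Of 15 measured members, 12 were higher, both over all rows and adjusted over the list alone, with a median log2 difference of 2.41. Musk, the receptor kinase that organises the postsynaptic membrane, was 13.1-fold higher (log2 difference 3.71 ± 0.12, SE), and Lrp4, its partner that binds agrin, was 7.02-fold higher. Rapsn, the scaffold that clusters the receptor, had a log2 difference of -0.04 ± 0.12 (SE; limma adjusted p = 0.842). Dok7, the adaptor that activates Musk, had one of -0.23 ± 0.11 (SE; limma adjusted p = 0.194), which reached -0.49 with an adjusted p of 0.0251 after quantile normalization and -0.36 with 0.0496 after median centring. Gabpa, an ETS factor subunit, had one of 0.13. Camera gave an adjusted p of 3.18e-09, and an adjusted p = 0.0635 with an estimated correlation.

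Genes known from subsynaptic nuclei rose in all 11 measured cases, also when adjusted over the list alone, with a median of 3.71. The list shares 4 genes with the receptor list. Prkar1a, a regulatory subunit of protein kinase A, was 18.2-fold higher (4.19 ± 0.09, SE), and Gramd1b, a sterol transfer protein gene, had a log2 difference of 4.62. Camera gave an adjusted p of 7.78e-13, with an adjusted p = 0.0964 with an estimated correlation. Of 19 genes of the synaptic basal lamina and membrane skeleton, 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median of 1.82. Utrn, which encodes the dystrophin relative utrophin, was 9.15-fold higher. Lama2, a laminin chain, and Nes, the intermediate filament nestin, had log2 differences of 3.43 and 4.95. Plec, the cytolinker plectin, fell by 0.32, and the integrin gene Itga7 had a difference of 0.38 that did not pass. Plec did not pass in any fit that omitted an array (adjusted p = 0.0652 to 0.117), and Itga7 passed in some other fits, such as with array weights (0.0367). The list had a camera adjusted p of 1.84e-12, with an adjusted p = 0.126 with an estimated correlation. Schwann cell and fibroblast markers were higher in the same arrays, with medians of 1.77 and 1.33.

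**Figure D2:**
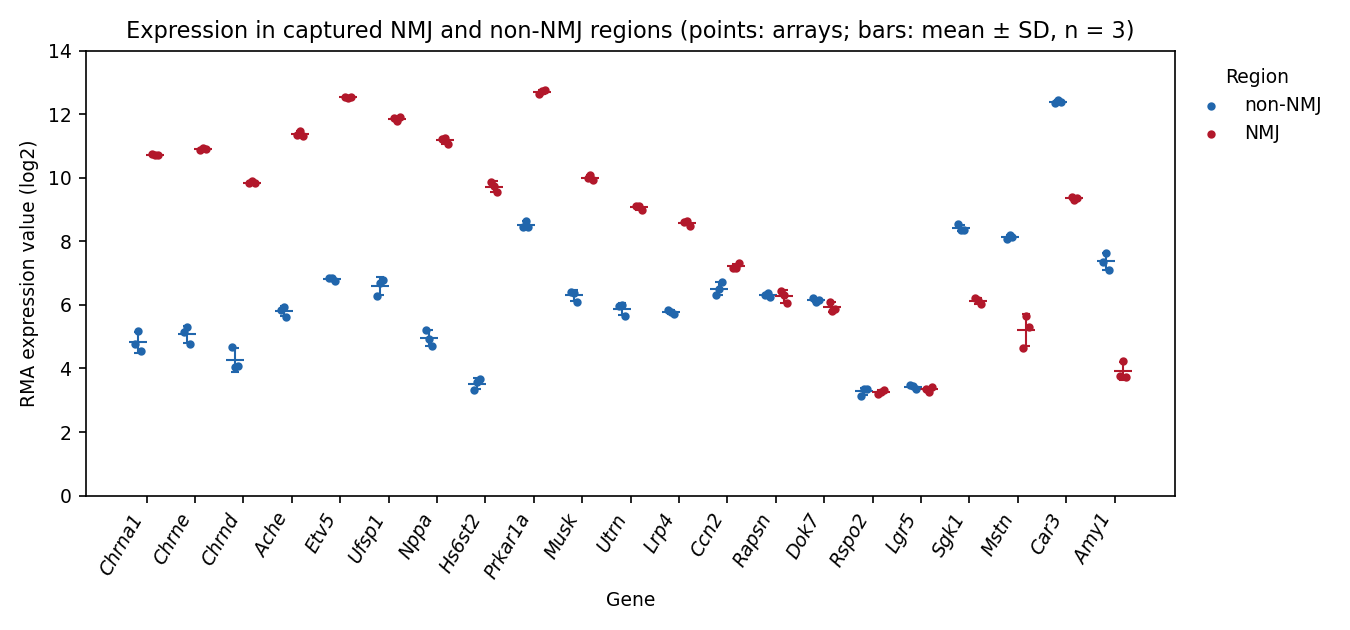
RMA expression on a log2 scale (y axis) for 21 genes (x axis) in non-NMJ (blue) and NMJ (red) regions; points are arrays, horizontal marks are means and bars are SD (n = 3). Chrna1 lay at 10.72 in NMJ and 4.83 in non-NMJ regions and Car3 at 9.35 and 12.40, while Rapsn, Dok7, Rspo2 and Lgr5 did not pass the test.

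Schwann cell markers rose in NMJ regions. Of 16 measured markers, 15 were higher, also when adjusted over the list alone. Pmp22, a myelin protein gene, rose by 3.11, the connexin gene Gjc3 by 4.03, S100b, a calcium-binding protein of glia, by 3.39, and the neuregulin receptor gene Erbb3 by 2.41 (log2). Erbb3 is also in the receptor list. The exception was Gfap, a glial filament gene, at 0.01. By camera, the adjusted p was 1.54e-09, with an adjusted p = 0.0532 with an estimated correlation. Transcripts of the motor axon and terminal were mostly dim, and their level over background is unknown. Of 16 members 0 rose and 1 fell, Uchl1, a neuronal hydrolase gene, by 0.51, and 0 passed when adjusted over the list alone. The median was -0.18 and the camera adjusted p was 0.0779, with an adjusted p = 0.212 with an estimated correlation. The synaptic vesicle genes Syt1 and Snap25 had differences of -0.28 and -0.20, and Stmn2, a tubulin-binding protein gene of neurons, had one of -0.32. Without the dimmest 50% of rows only 3 members were left, with a median of 0.11, so the list says little of a rise. Syt1 passed after median centring and without non-NMJ replicate 1, at adjusted p-values of 0.03 and 0.0471. Uchl1 passed without non-NMJ replicate 2 but not without any other array (adjusted p = 0.062 to 0.0867), nor without variance moderation (0.063).

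Most fibroblast markers rose, and some markers of vessel cells fell. Of 14 fibroblast markers, 11 rose, also when adjusted over the list alone. Col15a1, a basement membrane zone collagen gene, rose by 3.03, the proteoglycan genes Lum and Dcn by 2.42 and 1.61, and the collagen gene Col1a2 by 1.80. Mfap5, Pi16 and Cd34 were not called, at -0.18, 0.14 and -0.03. For the list, the camera adjusted p was 4.27e-07, with an adjusted p = 0.151 with an estimated correlation. Of 12 endothelial markers, 0 rose and 6 fell, with the same counts adjusted over the list alone and a median of -0.34. Omission of single arrays left 2 lower markers (NMJ replicate 1, 2 or 3 or non-NMJ replicate 2), 3 (non-NMJ replicate 1) or 5 (non-NMJ replicate 3). The growth factor receptor gene Flt1 fell by 0.76, the tight junction gene Cldn5 by 0.87, and the junction genes Pecam1 and Cdh5 by 0.38 and 0.39. Camera gave an adjusted p of 0.00302, with an adjusted p = 0.204 with an estimated correlation. Of 10 mural cell markers, 5 fell and 1 rose (5 and 2 adjusted over the list alone). Rgs5, a pericyte marker, fell by 1.18, Kcnj8 and Tagln by 0.88 and 0.76, and the proteoglycan gene Cspg4 rose by 1.57. Their camera adjusted p was 0.0423, with an adjusted p = 0.192 with an estimated correlation, and 0.0649 after median centring. The mural call also ended without NMJ replicate 1, non-NMJ replicate 2 or non-NMJ replicate 3, at 0.05, 0.0602 and 0.052. Pecam1 and Cdh5 passed without non-NMJ replicate 3 but not without any other array (adjusted p = 0.0683 to 0.108 and 0.0694 to 0.0944).

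Other cell types gave smaller groups of calls. Of 11 macrophage and leukocyte markers, 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Mrc1, the mannose receptor of resident macrophages, up by 1.85. Without NMJ replicate 1 or 2 the count of higher markers was 1, and without non-NMJ replicate 1 or 3 it was 2, as it was after quantile normalization. C1qc, a complement gene, and Cd163, a scavenger receptor gene, rose by 0.58 and 0.56, and the lysosomal marker Cd68 fell by 0.30. The list had a camera adjusted p of 0.0779, with an adjusted p = 0.323 with an estimated correlation. Of 10 satellite cell markers, Megf10 and Sdc4 rose by 0.86 and 1.25 and Myod1, a myogenic factor, fell by 0.75 (3 rose and 1 fell adjusted over the list alone). Vcam1 had a difference of 0.46 that did not pass, and the camera adjusted p was 0.175, with an adjusted p = 0.364 with an estimated correlation. The adipocyte list of 7 genes fell, with 2 members lower (3 adjusted over the list alone), a median of -0.24 and a camera adjusted p of 0.0159, or an adjusted p = 0.192 with an estimated correlation. Its 2 members were Car3, which muscle also expresses, and Fabp4, a lipid carrier gene also active in endothelium, which fell by 0.66. Cidec and Adipoq had differences of -0.63 and -0.24. Of 4 myotendinous junction genes, Adamts20 rose by 0.46, with the same count adjusted over the list alone, and Itgbl1, Fras1 and Tigd4 stood at 0.22, -0.04 and 0.04. That list had a camera adjusted p of 0.463, with an adjusted p = 0.619 with an estimated correlation, and its median of 0.13 became -0.01 after median centring. Cd68 did not pass in any fit that omitted an array (adjusted p = 0.0579 to 0.139). Without NMJ replicate 1 or 2, C1qc (adjusted p = 0.0741 and 0.0676), Cd163 (0.0818 and 0.073) and Adamts20 (0.0547 and 0.0642) did not pass either. The same held without non-NMJ replicate 1 for C1qc (0.0544), without non-NMJ replicate 2 for Cd163 (0.0632) and Adamts20 (0.0538), and without non-NMJ replicate 3 for C1qc (0.0517) and Cd163 (0.0511), and after quantile normalization for Cd163 (0.0618). Vcam1 passed without NMJ replicate 3 (0.0216), with array weights (0.0379), without the dimmest 25% of rows (0.0442) and among rows with a symbol (0.0304). Cidec passed after quantile normalization (0.0326) and median centring (0.0333), without the dimmest 50% of rows (0.0314) and among rows with a symbol (0.0339). The macrophage list passed without non-NMJ replicate 2 (0.0446).

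Genes of fast contraction and of oxidative energy supply fell in NMJ regions. Of 15 fast myofibre genes, 9 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.32; 14 fell after median centring, and 14 with an intensity trend and robust prior. Cacna1s, the calcium channel that senses voltage in the fibre, fell by 0.88, and Mybpc2, a myosin-binding protein gene, by 0.86. Actn3 and Mylpf, genes of fast sarcomeres, fell by 0.70 and 0.55. By camera, the adjusted p was 1.31e-06, with an adjusted p = 0.151 with an estimated correlation. Of 23 oxidative phosphorylation genes, 17 fell and 0 rose (18 and 0 adjusted over the list alone), with a median of -0.43. Omission of single arrays left 7, 9 and 10 lower genes (NMJ replicates 1, 2 and 3) and 11, 10 and 15 (non-NMJ replicates 1, 2 and 3). The succinate dehydrogenase genes Sdhd and Sdhc fell by 0.91 and 0.70, Ndufb8 of complex I by 0.70 and Cox7b of cytochrome oxidase by 0.83. For the list, the camera adjusted p was 1.30e-08, with an adjusted p = 0.126 with an estimated correlation. The medians of both lists stayed below 0 under quantile normalization (-0.20 and -0.32) and median centring (-0.46 and -0.57). Centring lowers every difference, so it could not have brought these medians to 0 and adds to the count of lower genes. Many of these rows were very bright, where array values compress differences.

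Of 12 glycolysis and glycogen genes, 5 fell and 0 rose (5 and 1 adjusted over the list alone), with a median of -0.24; 8 fell after median centring, and 8 with an intensity trend and robust prior. Phka1, a subunit of phosphorylase kinase, fell by 1.04, the branching enzyme gene Gbe1 by 0.80, the hexokinase gene Hk2 by 0.55 and Pgam2, a mutase gene of muscle, by 0.49. Camera gave an adjusted p of 0.00219, with an adjusted p = 0.247 with an estimated correlation, and it was 0.0621 after quantile normalization. Slow myofibre genes moved both ways: of 8, 3 rose and 2 fell (4 and 3 adjusted over the list alone). Casq2, a calcium store protein gene, Atp2a2, the slow calcium pump gene, and Tnni1, slow troponin I, rose by 2.45, 1.21 and 1.03. Myoz2 and Myl2, sarcomere genes of slow fibres and heart, fell by 1.43 and 0.48, and Myl2 did not pass without NMJ replicate 1 (adjusted p = 0.059) or 3 (0.0544). The median of 0.06 became -0.08 after median centring, and the camera adjusted p was 0.637, with an adjusted p = 0.847 with an estimated correlation. Of 20 ribosomal protein genes and related copies, 9 fell and 0 rose (10 and 1 adjusted over the list alone), with a median of -0.51. Rps3 fell by 0.98, Rps27l by 1.04, Rps9 by 0.57 and Rpl35a by 0.67. The list had a camera adjusted p of 0.00115, with an adjusted p = 0.151 with an estimated correlation; these genes have many pseudogene copies, so their array values are uncertain.

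Most genes listed for the response to denervation were higher in NMJ regions: of 12, 8 rose and 3 fell, with the same counts adjusted over the list alone and a median of 1.19. The list was not sorted by the direction of that response, so these counts do not show whether the genes moved as after denervation. The list shares Chrna1, Musk and Ncam1 with the synaptic lists. Runx1, a transcription factor, rose by 1.88. Fbxo32, a ubiquitin ligase gene of atrophy, Myod1 and Dach2, a corepressor gene, fell by 0.70, 0.75 and 0.42, and Gadd45a stood at -0.03. Dach2 passed without non-NMJ replicate 1 but not without any other array (adjusted p = 0.0756 to 0.154), nor after quantile normalization (0.058). By camera, the adjusted p was 0.00302, with an adjusted p = 0.212 with an estimated correlation.

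Signalling genes differed in their direction. Of 18 TGF-beta, YAP and CCN genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.65. Postn, the matrix protein periostin, was 31.9-fold higher, Ccn1 and the YAP relative Wwtr1 rose by 2.56 and 1.97, and Smad3, which transmits TGF-beta signals, fell by 1.52. Tgfb3, a ligand gene, also fell, by 0.73. Ccn2, a matricellular protein gene, was 1.63-fold higher (0.70 ± 0.13, SE; limma adjusted p = 0.0114), which did not pass after quantile normalization (adjusted p = 0.0791). The camera adjusted p of the list was 3.45e-04, with an adjusted p = 0.212 with an estimated correlation. Fibroblast markers were higher in the same arrays, 11 of 14, with a median of 1.33. Of 26 Wnt and R-spondin genes, 7 rose and 2 fell (8 and 3 adjusted over the list alone). The receptor genes Fzd7 and Lrp5 rose by 2.10 and 2.09, the ligand gene Wnt5a by 1.85 and the transcription factor gene Lef1 by 2.07. Lrp6, the relative of Lrp5, and the ligand gene Wnt4 fell by 0.48 and 0.56. Lrp6 did not pass without NMJ replicate 1 (adjusted p = 0.0577). Wnt4 passed without non-NMJ replicate 1 but not without any other array (0.102 to 0.131). The median of 0.04 became -0.05 and -0.10 under quantile normalization and median centring, and the camera adjusted p was 0.169, with an adjusted p = 0.247 with an estimated correlation. Rspo2, a secreted Wnt enhancer, and its receptor gene Lgr5 had log2 differences of -0.03 ± 0.10 and -0.08 ± 0.08 (SE; limma adjusted p = 0.871 and 0.53). Their mean levels stood at the 33.7 and 35.3 percentiles of all rows, and their level over background is unknown.

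Of 25 splicing and 3-prime-end regulators, 8 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.28. Mbnl2, a muscleblind splicing factor gene, rose by 0.93, the SR protein genes Srsf5 and Srsf6 by 1.16 and 1.24, and Ptbp2 by 0.81. Khdrbs3 and Mbnl1, both splicing factor genes, fell by 0.98 and 0.38. Without NMJ replicate 1, 5 genes rose, and Mbnl1 passed without non-NMJ replicate 3 but not without any other array (adjusted p = 0.056 to 0.0924). For the list, the camera adjusted p was 0.0159, with an adjusted p = 0.493 with an estimated correlation, and it was 0.0847 without the dimmest 50% of rows. Of 17 immediate early and heat shock genes, which respond to handling of tissue, 7 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 0.33. Egr2, also a Schwann cell marker, rose by 1.93, the chaperone gene Hsph1 and Fosl2 each rose by 1.26, and Nr4a1 rose by 0.68. Atf3 and Dusp1, stress-induced genes, fell by 1.30 and 0.45. Dusp1 did not pass without NMJ replicate 1, 2 or 3 or non-NMJ replicate 1 (adjusted p = 0.0556 to 0.0864). Camera gave an adjusted p of 0.0348, with an adjusted p = 0.348 with an estimated correlation, and it was 0.074 and 0.129 without the dimmest 25% and 50% of rows.

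**Figure D3:**
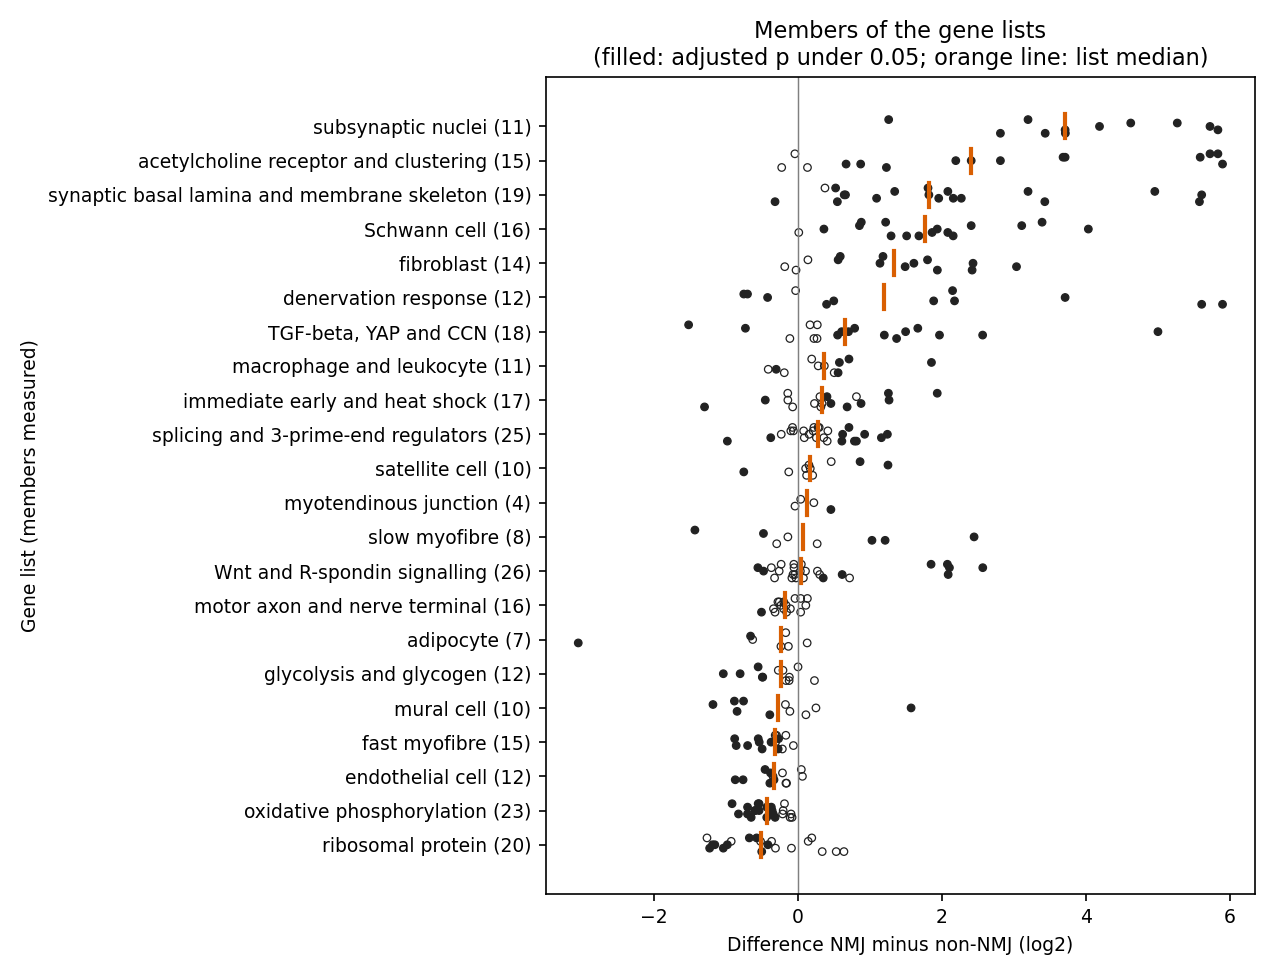
Log2 differences (NMJ minus non-NMJ, x axis) of the measured members of 22 gene lists (y axis, number measured in brackets); filled points had an adjusted p under 0.05 in limma, and orange lines are list medians. Medians ran from 3.71 for genes of subsynaptic nuclei to -0.51 for ribosomal protein genes.

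Camera called 16 of the 22 lists at the preset correlation, 9 higher and 7 lower in NMJ regions. With an estimated correlation it called 0 of them, while fry called 21. Among rows outside the named genes, 6577 rows with lower identifiers than the rest had no gene in the platform table. Their mean log2 value was 3.98, against 5.22 for rows with 1 symbol. Of these rows 835 (12.7%) were called, 529 higher and 306 lower, against 4165 (27.8%) of rows with 1 symbol. What these rows measure is not known here.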

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

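No alternative was added after the data were seen. Of 143 genes named here, those picked after their values were seen included, 109 kept their direction and their side of the threshold in each of up to 15 other fits that tested them (dim genes drop out of the filters on dim rows), and 34 did not. No row called both in the original fit and in another changed sign. With a 2-fold minimum, calls numbered 1641 (1285 higher and 356 lower), or 1815 (1403 and 412) with that minimum at an unadjusted p under 0.05. The fold minimum asks for more than the original threshold, while the unadjusted p asks for less. Lower rows numbered 3294 after quantile normalization and 3690 after median centring, which removes the higher median of the NMJ arrays. Omission of single arrays gave 3373 to 4706 calls, 2220 to 2879 higher and 1133 to 1888 lower, with fewer samples; without NMJ replicate 1, 2 and 3 the lower rows numbered 1133, 1315 and 1252. The mean correlation within regions exceeded that between them by 0.0281, and by 0.0471 and 0.0876 without the dimmest 25% and 50% of rows and 0.0359 in rows with a symbol; the omission of single arrays gave 0.0255 to 0.0305. An estimated correlation left 0 lists called. For the Schwann cell and mural cell lists the estimates were -0.0013 and -0.0149, below the preset 0.01. Their camera adjusted p still rose, from 1.54e-09 to 0.0532 and from 0.0423 to 0.192. High correlation between members is therefore argued against as the cause for these lists. The simulated list, with rows drawn independently, also went from 5.57e-18 to 0.0193. Omission of arrays left 15 or 16 lists, and macrophage genes passed without non-NMJ replicate 2 (adjusted p = 0.0446).

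Uncalled genes changed sign; the cause was not tested. Rapsn stood at 0.0081 with array weights. Without single arrays, Rapsn ranged from -0.1255 to 0.0657 (above 0 without NMJ replicate 3), Rspo2 from -0.0943 to 0.0076 (above 0 without NMJ replicate 1, non-NMJ replicate 2 or 3), Fras1 from -0.0973 to 0.0036 (above 0 without non-NMJ replicate 3) and Tigd4 from -0.3114 to 0.3727 (below 0 without NMJ replicate 2 or non-NMJ replicate 2). Tigd4 stood at -0.1009 after centring and -0.1538 with array weights. After quantile normalization Gfap, Pi16, Pkm, Shmt2 and Trib3 stood at -0.0386, -0.0767, -0.2462, -0.1246 and -0.0736. After centring Gabpa, Gfap, Pi16, Pkm and Shmt2 stood at -0.0072, -0.1278, -0.001, -0.1382 and -0.0302, and Pkm at -0.1063 with array weights. Without single arrays, Cd34 ranged from -0.09 to 0.0223, Gadd45a from -0.0877 to 0.0656, Gfap from -0.1131 to 0.1149, Pi16 from -0.0169 to 0.2473 and Pkm from -0.1649 to 0.0879. As a block, the replicate number gave 5064 calls, 4549 of them shared. It ended the calls of the mural list (adjusted p = 0.0664), Cd163 (0.0501), Cd68 (0.0819), Adamts20 (0.051), Dach2 (0.053), Plec (0.0597) and Wnt4 (0.085), and Cidec (0.017) and Itga7 (0.0438) passed. Deviations of same-numbered arrays correlated at 0.047, 0.035 and 0.184. Those of other pairs ran from -0.15 to 0.111, the highest for NMJ replicate 2 with non-NMJ replicate 1. These values do not settle whether the numbers mark pairs, and they were not taken as pairs. Without detection calls, signal over background limits what can be said of dim rows.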

Other observations

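The gene groups in the next paragraph, and the tests of cell share, Schwann cells, scaling, dilution and compression, were chosen after the results were seen. The scaling test was split by list after a joint test of both lists did not decide. The tests of neighbouring genes were set after adjacent genes (Ache and Ufsp1, and Hs6st2 with Gpc3 and Gpc4) had been noticed among the largest increases, before their own values were computed; the shuffles among genes of similar level were added after the first neighbour result.

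Genes induced by MAPK signalling rose in NMJ regions. All 10 measured members of a MAPK activity signature were higher, with a median log2 difference of 3.49, among them Dusp6, a phosphatase that restrains the pathway (5.18 ± 0.11, SE), Spry4, a feedback inhibitor (3.75 ± 0.16), and Ccnd1, cyclin D1 (3.32 ± 0.19). Etv4 and Etv5 belong to this group and to the receptor list. All 14 measured genes of protein folding in the endoplasmic reticulum rose, with a median of 1.51: Hspa5, the main chaperone there, was 4.50-fold higher, and the disulfide isomerase gene Pdia6 was 5.25-fold higher. Of 14 genes in a group for amino acid synthesis and transport, 10 rose. The group also held transcription factors and stress-response genes, Trib3 and Chac1 among them, and some of the 10 were of that kind. Asns, asparagine synthetase, was 16.3-fold higher and the transporter gene Slc7a5 was 7.62-fold higher, while Psph, Shmt2, Trib3 and Chac1 were not called, at -0.04, 0.11, 0.16 and -0.40; Chac1 passed as a lower gene in 6 other fits, such as after median centring (limma adjusted p = 0.0251). Of 18 genes of fatty acid and ketone use, 15 fell and 0 rose, with a median of -0.81. Ucp3, a mitochondrial carrier gene, was 4.06-fold lower, the ketone enzyme gene Bdh1 was 3.62-fold lower, and Acadvl, Hadha and Slc25a20 were not called, at -0.03, -0.11 and -0.34; Slc25a20 passed in 7 other fits, such as after median centring (limma adjusted p = 0.0141). Against 10000 random lists of equal size and similar level, the medians of these groups lay at the 100, 100, 99.97 and 0 percentiles. Members were picked after the top genes were seen, so this is no independent evidence. Fibroblast markers (11 of 14, median 1.33) and Schwann cell markers (15 of 16, median 1.77) were higher in the same arrays, and the cells that supplied these transcripts were not identified.

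The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05; 1 split, the real one, gave as many as 5364 calls, and the highest of the others gave 0.

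Schwann cell and fibroblast markers rose while endothelial markers did not. If other cell types kept their proportions, a lower share of fibre in the captured NMJ areas would raise their markers alike. The fibroblast median instead lay 1.674 above the endothelial median (permutation p = 0.00093, both directions tested), and 0 endothelial markers rose. These lists were compared after they were seen to differ, and their genes are not independent, so the p restates the pattern. The values argue against that simple form as the whole cause. A lower fibre share with changed proportions of the other cells stays open. That 15 of 16 Schwann cell markers rose, myelin genes included, restates the pattern, so whether Schwann cells captured with the junctions or another source supplied them stays open; Pmp22 reached 10.37 and Mbp 6.80 in NMJ regions, from 7.27 and 4.72. Erbb3 and Egr2 are also in other lists, and how much of each marker comes from fibres was not measured. Whether fibroblasts at the junction or fibre nuclei supply the matrix transcripts stays open.

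The fast myofibre, oxidative phosphorylation and glycolysis lists fell by camera at the preset correlation. With an estimated correlation, camera called none of them (adjusted p = 0.151, 0.126 and 0.247). Glycolysis also lost its call after quantile normalization (camera adjusted p = 0.0621) and was left out of the scaling test. Scaling is argued against as the whole cause for oxidative phosphorylation. Its median lay at -0.323 after quantile normalization, with 14 genes lower and 0 higher (camera adjusted p = 0.000171). That was nearer 0 than the original -0.432, so a part due to scaling stays open. Median centring lowers every difference by the 0.139 by which NMJ medians were higher. Its medians (-0.571, and -0.455 for fast myofibre genes) could therefore not speak for scaling. The fast myofibre list also stayed lower after quantile normalization (median -0.195, 6 genes lower and 0 higher, camera adjusted p = 0.00424). Its -0.195 narrowly missed the size set for the test, so a part of its fall due to scaling stays open. Dilution of all fibre RNA by 1 factor would move members alike only if the other captured cells did not express them, which was not measured. The 31 members under log2 12 differed beyond their errors (chi-square heterogeneity p = 4.56e-42), with 16 apart from the common difference of -0.492. That p is approximate, since the errors come from 3 arrays per region and genes are not independent. A line on level left a heterogeneity p of 1.1e-33 without Pkm, omitted because it stood out, and 1.8e-38 with it. Members that other cells also express would move less, so this spread cannot decide on dilution. Compression of bright rows could make the decreases look smaller: over 50 genes, which are not independent, the difference lay nearer 0 in brighter rows (Spearman rho = 0.467, Pearson r = 0.376, permutation p = 0.00089), with medians of -0.54 under log2 12 and -0.274 above. Dilution, gene-specific decreases and a mixture of both stay open.

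Neighbouring genes differed alike to a small degree. Over 13051 adjacent pairs without shared name stems, Spearman rho was 0.049, above the highest of 1000 shuffles of gene order (0.029); p = 0.001 is the smallest these permutations can give. Shared expression level is argued against as the whole cause, since shuffles among genes of similar level reached at most 0.032 (permutation p = 0.001, again the smallest). Among 160 neighbours of the 92 genes at least 8-fold higher, 45 (28.1%) were called higher, against 17.5% of all genes and 12.9% to 24.7% in random sets. The random sets were not matched for expression level, so level may account for this excess. Read-through transcripts, overlapping probes and shared regulation may each contribute and were not tested.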
